A study of Mus musculus with 42 samples.

How the data were processed

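The samples were cultures of mouse bone marrow cells grown in medium with a mixture of haematopoietic cytokines, from wild-type (WT) mice and from mice in which both copies of Cdk2 carry the dTAG sequence (CDK2-dTAG). The dTAG sequence is a protein tag that the small molecule dTAG-13 links to the cereblon ubiquitin ligase, so that the tagged protein is degraded. Cells were left untreated, or were given DMSO (the solvent) or 250 nM dTAG-13. The labels list 42 samples in 14 groups of 3, at 2, 6 and 24 h. Libraries were made from polyadenylated RNA with a kit that reads 3′ ends of transcripts, so expression was read near the 3′ end of each gene. The labels number the samples of a group 1 to 3 but do not say that they come from separate mice.

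The only file was a table of 25655 genes with the authors' own summary. It held no values per library. It had 6 group columns and 6 comparisons. The 4 columns of DMSO and dTAG-13 groups are headed 24 h, and the 2 untreated columns are headed without a time; the labels give 24 h for the untreated samples. No group headed 2 h or 6 h had a column, and those 8 groups were not analysed here. The group columns are the authors' values, rounded to whole numbers. They are headed TPM in the file, but their totals were 6107213 to 6283923, so they are not TPM, and they are treated as a signal whose scale is per the file headers only partly given. The authors' deposited baseMean is also a signal on that scale. The deposited dispersion is a score of the authors' model with an upper limit: 7512 genes are listed at exactly 59 and none is higher. The deposited fold columns are a ratio, and the deposited log2 columns are their logarithm; the direction is the first group named over the second. The deposited p-value columns come from the authors' test, which is not named in the sources used here. The submitters' processing notes name Salmon, without a version; the genome build, the gene annotation, the filter on low values and the size factors are not given in the sources used here. The deposited adjusted p equalled a Benjamini-Hochberg adjustment over the genes that had one. The depth of each library is unknown, so no counting interval or detection floor is given. The gene AY036118, which overlaps ribosomal RNA, held 20.8% of the column totals on average, and the top 10 genes 28.8%. Of the gene IDs, 25619 (99.9%) matched GENCODE release M21, which was used for gene classes and for the position of Cdk2.

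The design fixed before the data were examined assumed a table of counts per library. The tests per library that it named could not be run on a table of group values, so the comparisons reported here are the authors' own, and every value printed from that table is the authors'. A gene was called where the authors' adjusted p was below 0.05. The rest was computed here. The standard error that a deposited comparison implies was taken as its log2 fold divided by the normal quantile of its p-value, which assumes a Wald test. Drug effects were compared between genotypes, and genotype effects between untreated and DMSO cells, by the difference of the deposited log2 folds over the root of the summed squared standard errors, two-sided, adjusted over genes with baseMean of 10 or more. The number of libraries per group that a comparison implies was computed from these standard errors, the deposited dispersion and the group values, over genes with baseMean of 200 or more, group values of 100 or more and an absolute log2 fold of 0.1 or more. Fixed gene lists (33, written before the data were examined) were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the implied z-values, with a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists of a comparison. A correlation between genes could not be estimated without values per library. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

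Named genes followed a rule fixed in advance. For each drug comparison these were Cdk2 and up to 10 genes in each direction with the largest log2 fold among called genes at 0.001% of the column total or more in the higher group; other comparisons took 5 in each direction. Where fewer than 3 genes passed, the 3 genes with the smallest p were named. Up to 4 called members were named per list, or its highest member where none was called. The part of the rule that asked every replicate to separate could not be applied. Predicted gene models were counted but not named, except where a count was 5 or fewer.

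The computations were tested on simulated data. Counts were drawn for 12416 genes from the deposited means and dispersions, with 200 genes changed in the comparison of dTAG-13 with DMSO in CDK2-dTAG cells, and a negative binomial model was fitted. The layout was chosen after the table was seen, from the upper limit of 59 on the deposited dispersion, which was read as the number of libraries in the authors' model because a common negative binomial package sets its limit so, and from the precision of the deposited p-values. Agreement with either is therefore no independent support for it. The 42 labelled libraries with the 3 times pooled and a time term would give 3.00 libraries per group for the genotypes in untreated cells and 4.00 for untreated against DMSO in each genotype. Values of 2.40, 3.09 (WT) and 4.15 (CDK2-dTAG), close to those implied by the table, came from a layout of 59 libraries, with 2 untreated WT libraries in place of 3 and 18 further libraries that the labels do not list. Whether the authors used it is not known. In that layout, the model did not converge for 2 genes, which were left out; a first version of the fit without step control diverged for some genes and was replaced before any result was taken from it. For that comparison, among changed genes with baseMean of 100 or more, 19% of 21 genes were called at a 1.5-fold change, 69% of 35 at 2-fold, 92% of 26 at 3-fold and 100% of 24 at 4-fold. Of the 109 genes called, 12.8% had not been changed, above the share that the threshold aims at. In a layout with the 24 h libraries alone, the shares called were 0% of 21, 23% of 35, 62% of 26 and 79% of 24. The test of list enrichment called 0 of 33 lists in each of 2 unchanged simulations of the WT drug comparison. The simulated genes were drawn independently of each other, so this does not check the list test against correlation between genes.

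Alternatives were chosen after the table was seen, because those planned needed values per library. They were other sets of genes for the adjustment, a threshold of 0.1, a standard error scaled to 3 libraries per group, the ratio of the group values in place of the deposited fold for untreated cells, and other settings of the list test. For the ratio, the standard error came from the deposited dispersion. It assumed 2 untreated WT, 3 untreated CDK2-dTAG and, in each genotype, 9 DMSO libraries.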

Results

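The study used mouse bone marrow cultures to ask how removal of CDK2, a cyclin-dependent kinase that acts in S phase, changes gene expression. RNA was measured by 3′ end sequencing in WT and CDK2-dTAG cells that were untreated or received DMSO or 250 nM dTAG-13. The labels give 3 samples to each of 14 groups. The authors' deposited table gives pooled values for 6 groups, 4 headed 24 h and the 2 untreated ones without a time, and no value per library, so no spread between replicates can be printed and library depth is unknown. Column totals of the group values ranged from 6107213 to 6283923. The precision of the deposited p-values did not match 3 libraries per group: the median number that they imply was 9.01 for dTAG-13 against DMSO in CDK2-dTAG cells, 8.99 in WT cells and 9.01 for the genotypes in DMSO. It was 2.40 for the genotypes in untreated cells, 3.09 for untreated against DMSO in WT cells and 4.15 in CDK2-dTAG cells.

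Cdk2 was examined first, because the tagged gene checks the labels as far as the tag alters its transcript. The degrader acts on the protein, so its mRNA need not move with the drug. Cdk2 (ENSMUSG00000025358) lies on chromosome 10 from 128697939 to 128705031 in GRCm38, by the GENCODE annotation. In the authors' deposited table, Cdk2 had values of 234, 226 and 221 in untreated, DMSO and dTAG-13 WT cells and of 174, 152 and 168 in the matching CDK2-dTAG cells. The log2 fold of WT over CDK2-dTAG in DMSO was 0.57 in the authors' deposited table (p-value 0.00325), and it did not pass adjustment (adjusted p = 0.473). For dTAG-13 over DMSO, the authors' deposited table gave a log2 fold of 0.14 in CDK2-dTAG cells (adjusted p = 1) and of -0.03 in WT cells (adjusted p = 1). The 95% intervals computed from those p-values were -0.24 to 0.53 and -0.40 to 0.35.

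The first question was which transcripts change with dTAG-13 in CDK2-dTAG cells. The data hold no protein values, so the extent of CDK2 loss is not known here. In CDK2-dTAG cells, no gene at 0.001% of the column total or more in both groups was called between dTAG-13 and DMSO, out of 7872 such genes; 93 of them had an unadjusted p below 0.05. Over all genes, the authors' deposited table called 8 genes higher and 27 lower with dTAG-13. Of the 24604 genes with a p-value, 419 had an unadjusted p below 0.05. The counts of 93 and 419 are smaller shares than the 0.05 that evenly spread p-values would give, so they show no excess of small p-values. All 35 called genes had a value of 1 or less in one of the groups. Outside predicted models, the genes with the smallest p were Exoc3l2, Atp1b4 and AW121686. Each was listed at 0 with dTAG-13 and at 2, 1 and 1 with DMSO in the authors' deposited table, so no fold is given. Adjustment over genes with baseMean of 10 or more left 0 genes.

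No cell cycle list passed its test with the degrader. Mcm3, a subunit of the replicative helicase, had values of 1175 with dTAG-13 and 1149 with DMSO in CDK2-dTAG cells in the authors' deposited table. Top2a, a mitotic topoisomerase, had 2392 and 2517, Ccnd2, which encodes cyclin D2, had 3691 and 3552, and Cdkn1a, which encodes the CDK inhibitor p21, had 1710 and 1639 (authors' deposited table, adjusted p = 1 for each). None of the 44 tested E2F target and DNA replication genes was called, over all genes or adjusted over the list alone, and their median log2 fold was 0.07 (limma cameraPR, adjusted p = 0.52). The 45 genes of G2/M and mitosis had a median of -0.06 (adjusted p = 0.707), and the 28 p53 targets had a median of 0.04 (adjusted p = 0.707), again with 0 members called. None of the 33 lists passed in this comparison; the smallest adjusted p was 0.52. Absence of a call is limited by power: in simulated libraries with the precision of the table, 19% of genes with baseMean of 100 or more were called at a 1.5-fold change and 69% at 2-fold. With baseMean of 10 or more, these shares were 8% and 50%. They hold for a change of the same size at all 3 times. Simulated 24 h libraries alone gave 0% and 23% with baseMean of 100 or more. In each of these simulations other genes changed too, some by 3-fold or 4-fold. The adjustment covered at most 12416 genes, against 19650 in the table. Both loosen the cutoff for a call. Small p-values were also scarcer in the table than evenly spread p-values would give. The shares are therefore not the power for a lone changed gene in the table, which may be lower.

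WT cells, which lack the tag, show what dTAG-13 does without its target. Cox20, which encodes an assembly factor of cytochrome c oxidase, was the single called gene with both groups at 0.001% or more; its values were 220 with dTAG-13 and 125 with DMSO in the authors' deposited table (log2 fold 0.82, adjusted p = 0.0449). Its value was 195 in untreated WT cells, and 189, 211 and 183 in untreated, DMSO and dTAG-13 CDK2-dTAG cells. The WT DMSO value was thus the lowest of the 6 groups. The authors' deposited table called 44 genes higher and 43 lower in WT cells, and 86 of the 87 had a group value of 1 or less. Amd-ps3, a pseudogene, was listed at 83 with dTAG-13 and at 0 with DMSO in the authors' deposited table. Outside predicted models, the 3 genes with the smallest p, Prob1, Nectin3 and Pde11a, had values of 0 to 2 in both groups of that table, so no fold is given. Adjustment over genes with baseMean of 10 or more left 3 genes, and Cox20 was not among them. None of the 33 lists passed; the NF-kB and inflammatory cytokine list was nearest, with a median log2 fold of -0.11 over 33 genes (cameraPR, adjusted p = 0.148).

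The drug effects of the genotypes were compared gene by gene. Of 12380 genes tested, 3 differed, and 0 of the 7562 genes at 0.001% or more in all 4 groups did (smallest adjusted p = 0.765). An unadjusted p below 0.05 was found for 334 of the genes tested (2.7%), against 5.3% of unchanged genes in the simulated layout of 59 libraries. The simulated p-values thus did not match those of the table in this respect. Across those 7562 genes, which are not independent replicates, the drug effects had a Pearson correlation of 0.004 and a Spearman correlation of 0.006, and 49.7% had the same sign.

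**Figure D1:**
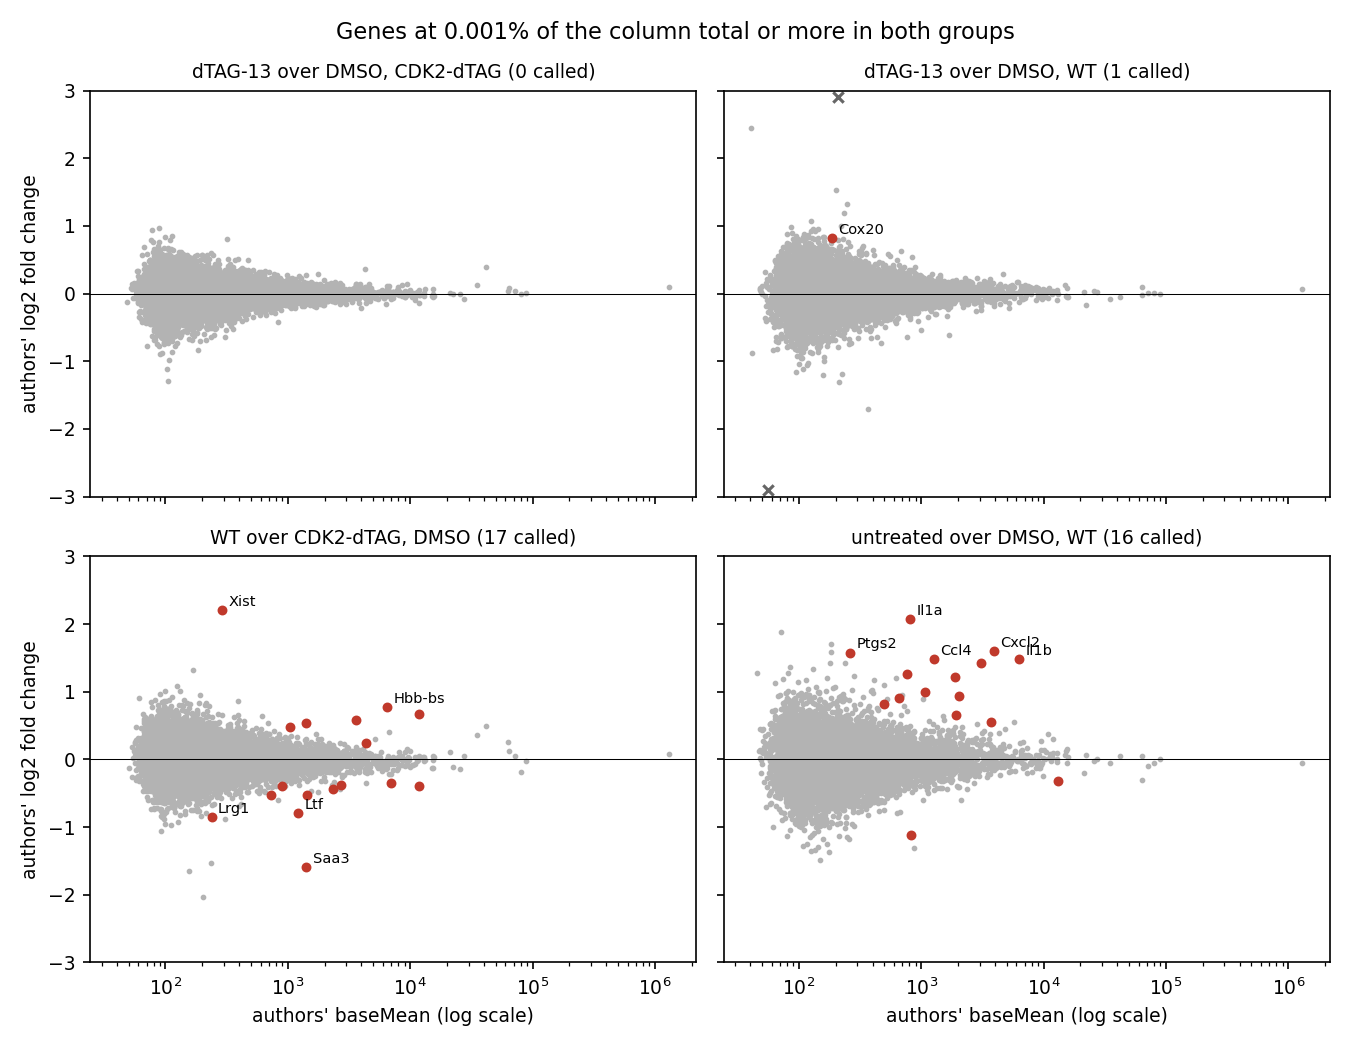
Authors' log2 fold change (vertical axis, limited to 3 in each direction) against the authors' baseMean (log scale) for genes at 0.001% or more in both groups. Each point is a gene, red points were called, and crosses at the edge are genes beyond the axis; 0 genes were called for dTAG-13 in CDK2-dTAG cells, 1 in WT cells, 17 between genotypes in DMSO and 16 between untreated and DMSO WT cells.

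The genotypes differed in cells that received no degrader. In DMSO, 10 genes were higher in CDK2-dTAG cells and 7 in WT cells among called genes at 0.001% or more in both groups. Saa3, an acute phase serum amyloid, differed most in p: its values were 731 in WT and 2164 in CDK2-dTAG cells (authors' deposited table, log2 fold of WT over CDK2-dTAG -1.59, adjusted p = 1.21e-38). Some neutrophil genes were also higher in CDK2-dTAG cells. Ltf (lactoferrin) had a log2 fold of -0.79, Ngp of -0.39, Camp (the cathelicidin precursor) of -0.38, Cd177 of -0.53 and BC100530 of -0.35 in the authors' deposited table, with adjusted p from 2.27e-10 to 0.014. Lrg1, a secreted glycoprotein of neutrophils (-0.85), the short-chain fatty acid receptor Ffar2 (-0.52), the progenitor surface gene Ly6a (-0.44) and the primary granule protease Prtn3 (-0.39) lay in the same direction in the authors' deposited table. Of 30 neutrophil genes tested, 5 were called lower in WT cells and 0 higher, and 7 were lower adjusted over the list alone (median log2 fold -0.13, cameraPR, adjusted p = 1.92e-11). S100a8 and S100a9, abundant neutrophil transcripts of the same list that were chosen after their values were seen, had log2 folds of -0.18 and -0.02 in the authors' deposited table and were not called. Mmp8, another member chosen in that way, had values of 13087 in WT and 13118 in CDK2-dTAG cells in the authors' deposited table (log2 fold -0.004). The list of granulocyte-monocyte progenitors and primary granules was also lower in WT cells (median -0.14, 1 member called, adjusted p = 1.46e-05), and cytosolic ribosomal proteins were lower by less (-0.05, adjusted p = 4.76e-05). The interferon list (0.14, adjusted p = 0.0049) and mitochondrially encoded genes (0.04, adjusted p = 0.00905) were higher in WT cells, with 0 members of these 3 lists called over all genes; adjusted over the list alone, 3 mitochondrially encoded genes were higher in WT cells and no ribosomal or interferon gene passed. In untreated cells, none of these 3 lists passed: ribosomal proteins had a median of 0.03 (adjusted p = 0.379) and mitochondrially encoded genes of -0.04 (adjusted p = 0.732), both of the opposite sign, and interferon genes of 0.03 (adjusted p = 0.851). With an inter-gene correlation of 0.05, the interferon and mitochondrial lists also missed the threshold in DMSO, and the mitochondrial list missed it with ranks.

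Globin transcripts were higher in WT cells. In DMSO, Hba-a2 had values of 13916 in WT and 8726 in CDK2-dTAG cells and Hbb-bs of 8068 and 4700, with log2 folds of 0.67 and 0.78 in the authors' deposited table (adjusted p = 2.27e-10 and 1.97e-09). Hba-a1 and Hbb-bt had log2 folds of 0.59 and 0.54 in the authors' deposited table. Hba-a1 is a near-identical copy of Hba-a2, and Hbb-bt of Hbb-bs, so reads may be split within each pair. The 4 globin genes were the called members among 23 tested erythroid and haem synthesis genes, over all genes and adjusted over the list alone (median 0.24, adjusted p = 2.12e-08). The list missed the threshold with ranks (adjusted p = 0.0706). Xist, the RNA of the inactive X chromosome, had values of 478 in WT and 107 in CDK2-dTAG cells in the authors' deposited table (log2 fold 2.20, adjusted p = 7.9e-12). The median of the 6 sex-linked genes was -0.20 while their test pointed to WT (adjusted p = 0.0425); the list missed the threshold with ranks and with an inter-gene correlation of 0.05.

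Over all genes, the authors' deposited table called 61 genes between genotypes in DMSO, 23 higher and 38 lower in WT cells; 44 of them had a group value of 1 or less. The p-values of single genes in this comparison imply 9.01 libraries per genotype. The labels number 3 samples per group and do not say that they come from separate mice. Cultures of 1 mouse may thus count as separate libraries, and these p-values may not measure the spread between mice. With the standard error scaled to 3 libraries per group, 4 genes passed, namely Saa3, Xist, Hba-a2 and Ngp. Hbb-bs and Ltf missed the threshold with that scaled error (adjusted p = 0.0743 and 0.184). The list tests set members against the other genes with a preset inter-gene correlation. Their adjusted p-values therefore do not measure the spread between libraries or mice.

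Untreated cells gave the genotype comparison without DMSO. Saa3 was again lower in WT cells, with values of 692 and 1675 (authors' deposited table, log2 fold -1.28, adjusted p = 0.00017), and it was the single called gene at 0.001% or more in both groups. Rps12-ps11, a pseudogene, and AK157302 were listed at 62 and 27 in WT and at 0 in CDK2-dTAG cells in the authors' deposited table. The erythroid list was higher in WT cells (median 0.53, adjusted p = 0.000571) and the neutrophil list lower (median -0.12, adjusted p = 0.000863), with 3 and 2 members passing adjusted over the list alone. The lists of primary granules (median -0.14) and of sex-linked genes (0.50) also passed (adjusted p = 0.00383 for each), the former not with an inter-gene correlation of 0.05 and the latter not with ranks. The sex-linked list joins Xist with Y-linked genes, which a different share of female mice would move in opposite directions. Its pass here and in DMSO therefore shows no common shift of its members. All 17 genes called in DMSO at this level had the same sign in untreated cells. Untreated and DMSO samples carry the same replicate numbers, and the labels do not say whether they share mice. That count may therefore not be independent evidence of a genotype effect. Across the 7374 genes at 0.001% or more in all 4 groups, the Pearson correlation of the genotype effects was 0.054, and 50.2% had the same sign. The difference of the genotype effects between untreated and DMSO cells passed for 4 of 12390 genes and for 0 of 7374 at 0.001% or more in all groups.

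**Figure D2:**
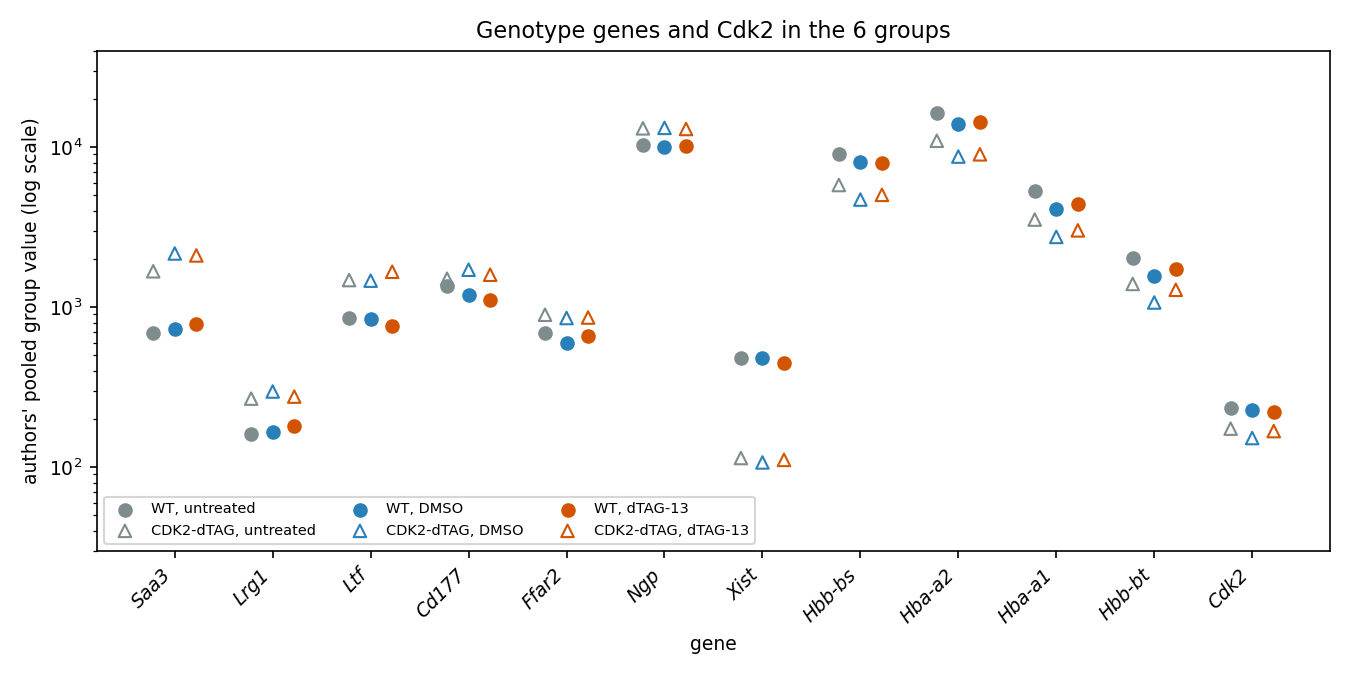
Authors' pooled group values (log scale) of the genes named for the genotype comparison and of Cdk2. Filled circles are WT and open triangles CDK2-dTAG cells, colours give the treatment, and the table gives no error; Saa3 lay at 692 to 786 in the WT groups and at 1675 to 2164 in the CDK2-dTAG groups.

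Untreated cells were compared with DMSO cells of the same genotype; the deposited folds of this comparison depart from the ratios of the group values by a shift common to both genotypes, so they are not a measure of the solvent alone. Inflammatory transcripts were higher in untreated cells of both genotypes. In WT cells the authors' deposited table gave log2 folds of untreated over DMSO of 2.07 for Il1a, 1.58 for Ptgs2, 1.60 for Cxcl2, 1.48 for Ccl4 and 1.48 for Il1b, with adjusted p from 9.27e-11 to 0.041. In CDK2-dTAG cells the same genes had 2.08, 1.79, 1.70, 1.61 and 1.52 in the authors' deposited table, with adjusted p from 1.05e-18 to 0.000177. Il1a and Il1b encode interleukin 1 cytokines, Cxcl2, Ccl3 and Ccl4 chemokines and Ptgs2 cyclooxygenase 2. Of 33 NF-kB and inflammatory cytokine genes tested, 8 were called higher in untreated WT cells and 11 in untreated CDK2-dTAG cells, and 13 and 15 adjusted over the list alone; none was called lower (medians 0.57 and 0.63, cameraPR, adjusted p = 3.25e-57 and 1.16e-55). The monocyte receptor Cd14 had log2 folds of 1.26 in WT and 1.10 in CDK2-dTAG cells in the authors' deposited table (adjusted p = 0.000862 and 0.000346); the log2 ratios of its group values were 0.46 and 0.34, and neither passed (adjusted p = 1). Most of the 28 monocyte and macrophage genes tested lay in the other direction, with 10 and 9 higher in untreated cells (medians -0.16 and -0.18), and that list did not pass (adjusted p = 0.762 and 0.351).

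Interferon genes lay in the opposite direction. Ifit3, an interferon-induced gene, had log2 folds of -1.11 in WT and -0.95 in CDK2-dTAG cells in the authors' deposited table (adjusted p = 0.000989 and 0.00072); the log2 ratios of its group values were -0.60 and -0.41, and neither passed (adjusted p = 1). The interferon list had medians of -0.23 (adjusted p = 7.84e-08) and -0.20 (adjusted p = 0.00111) over 42 genes, with 1 called in each genotype. On the ratio of the group values, the medians were -0.10 in WT and -0.07 in CDK2-dTAG cells and the list passed in neither (adjusted p = 0.126 and 0.831); with an inter-gene correlation of 0.05 it passed in WT cells and missed the threshold in CDK2-dTAG cells (adjusted p = 0.0722). Cholesterol synthesis genes had a median of -0.32 in WT cells (adjusted p = 2.32e-05, 0 members called) and of -0.24 in CDK2-dTAG cells (adjusted p = 0.0587). Mmp8 was lower in untreated WT cells (authors' deposited table, log2 fold -0.32, adjusted p = 0.0128), and Gda and Msrb1 in untreated CDK2-dTAG cells (-0.62 and -0.48). A pair of pseudogenes was also named by the rule: Gpx4-ps2, with values of 22 untreated and 262 with DMSO in WT cells, and Rps12-ps16, listed at 0 and 78 in CDK2-dTAG cells of the authors' deposited table. Called members of other lists in untreated CDK2-dTAG cells included the cystine transporter Slc7a11 (log2 fold 0.92), the adhesion molecule Vcam1 (1.10), the matrix protease Mmp13 (0.84), thrombospondin 1 (Thbs1, 0.62) and the apoptosis regulator Bcl2a1b (0.49), by the authors' deposited table. On the ratio of the group values these 5 genes had log2 values of 0.16, 0.67, 0.49, 0.36 and 0.15, and none passed (adjusted p = 1). Immediate early genes (median 0.26, adjusted p = 0.00791), apoptosis regulators (0.21, adjusted p = 0.00963) and the mast cell, basophil and eosinophil list (0.20, adjusted p = 0.000443) passed there, the last with Ccl3 as its called member. That list also passed in WT cells (0.08, adjusted p = 0.000712). Mitochondrially encoded genes were higher (0.25, adjusted p = 1.56e-05) and cytosolic ribosomal proteins lower (-0.10, adjusted p = 0.0013) in untreated CDK2-dTAG cells, with 0 members called. With an inter-gene correlation of 0.05, the immediate early, apoptosis and ribosomal lists missed the threshold in CDK2-dTAG cells. On the ratio of the group values the apoptosis list missed it, and the mast cell list missed it in both genotypes, as it did with ranks.

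Over all genes, the authors' deposited table called 22 higher and 17 lower in untreated WT cells and 31 higher and 18 lower in untreated CDK2-dTAG cells. At 0.001% or more in both groups, 16 (14 higher and 2 lower) and 34 (31 higher and 3 lower) genes were called, 15 in both, and all 35 called in either had the same sign in both genotypes; both folds share the shift from the group ratios, so this count is not independent evidence of agreement. The Pearson correlation of the effects across 7374 genes was 0.246 with a covariance of 0.0278. Libraries simulated without a solvent effect, with untreated cells at 24 h and a shared fitted time term, gave 0.094 and 0.0146. With untreated cells simulated at the mean of the times, both folds also held the time shift, and the values were 0.123 and 0.0203. The simulated values cover 6967 and 6927 genes under another filter and rest on an assumed time shift. They are therefore no bound for the observed values.

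The deposited folds of untreated cells are not the ratios of the deposited group values. Il1a had values of 1202 untreated and 792 with DMSO in WT cells in the authors' deposited table, a log2 ratio of 0.60 against the deposited log2 fold of 2.07. A test on the ratio of the group values rests on assumed numbers of libraries, and whether the authors used these is not known. In that test, 0 genes passed in WT cells and 3 in CDK2-dTAG cells, and the inflammatory list passed in both (adjusted p = 1.47e-07 and 2.01e-09) with medians of 0.22 and 0.29. Cholesterol synthesis genes also passed in WT cells, and immediate early, ribosomal and mitochondrial genes in CDK2-dTAG cells; the interferon and mast cell lists passed in neither genotype, and apoptosis regulators no longer passed in CDK2-dTAG cells.

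**Figure D3:**
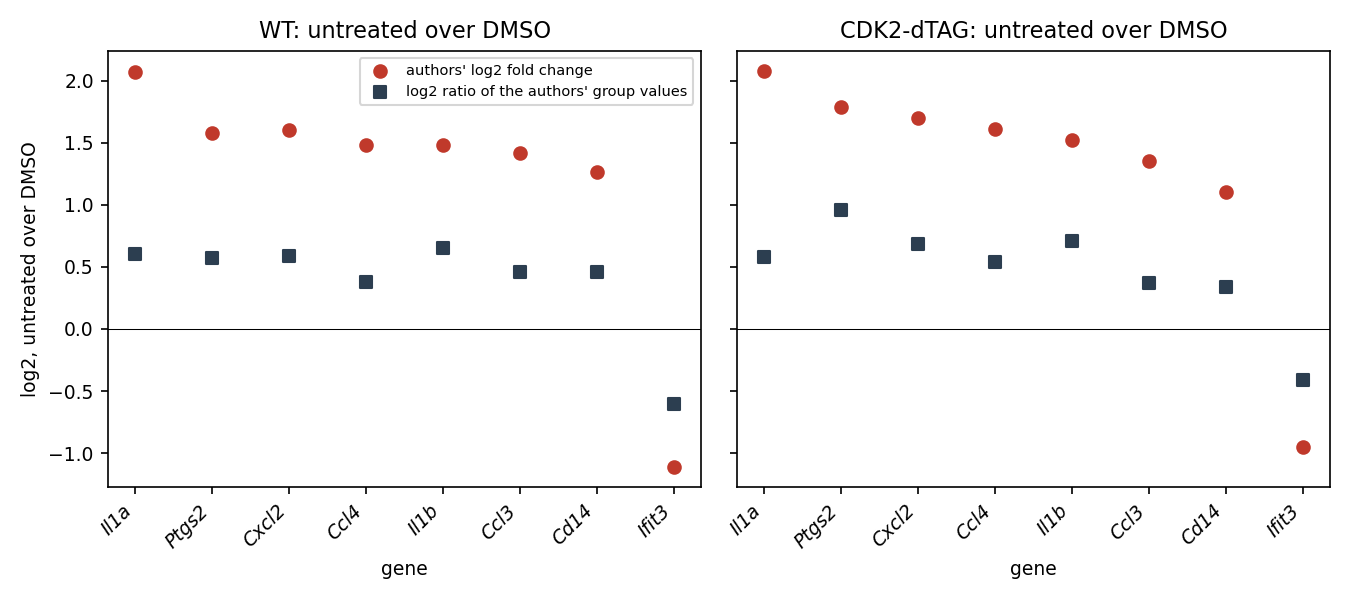
Log2 of untreated over DMSO for 8 named genes in WT (left) and CDK2-dTAG cells (right). Circles are the authors' log2 fold changes and squares the log2 ratios of the authors' group values, without error bars because the table holds no replicates; in WT cells Il1a lay at 2.07 and 0.60.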

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

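The tests of differences were chosen after the table was seen. Drug effects differed between genotypes past the threshold for 3 genes, all predicted models with at least one group listed at 0. These genes, named because the count is small, were Gm14414 (adjusted p = 2.67e-08), Gm20633 (adjusted p = 0.000268) and Gm15922 (adjusted p = 0.0385). Gm14414 had values of 54 with DMSO and 0 with dTAG-13 in WT cells, and of 15 and 48 in CDK2-dTAG cells, in the authors' deposited table.

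Genotype effects differed between untreated and DMSO cells for 4 genes. Rps12-ps11 (adjusted p = 0.00833) was listed at 62 in untreated WT and 0 in untreated CDK2-dTAG cells, and at 52 and 22 with DMSO, in the authors' deposited table. Gm13611 (adjusted p = 0.00164), Gm10108 (adjusted p = 0.00177) and Gm9385 (adjusted p = 0.00418) were each listed at 0 in untreated WT cells, and were named after their values were seen. Groups of 3 samples without values per library left outlying libraries untested.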

How the results depend on the processing

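No paired analysis was possible because the table holds no values per library. For the same reason the comparisons with other settings fixed in advance (other counting tools, normalizations, filters, prior counts, samples in the fit, replicate blocks, an estimated inter-gene correlation, a self-contained list test and leaving out each replicate) and other splits of the samples were not run, and the 2 h and 6 h comparisons were not analysed here. All alternatives below were chosen after seeing the data. Adjustment over genes with baseMean of 10 or more gave 0 calls for the drug in CDK2-dTAG cells (35 as deposited), 3 in WT cells (87), 18 for genotype in DMSO (61), 7 in untreated cells (13) and 24 for untreated against DMSO in WT cells (39). With baseMean of 50 or more these were 0, 0, 17, 4 and 22, and with both groups at 0.001% of the column total or more 0, 0, 17, 1 and 17; fewer genes near 0 entered by construction. Untreated against DMSO in CDK2-dTAG cells gave 45, 37 and 37 calls with these 3 sets of genes (49 as deposited). The standard error scaled to 3 libraries per group gave 0, 2 and 4 calls for the drug in CDK2-dTAG cells, in WT cells and for genotype in DMSO. The ratio of the group values gave 3 calls (Acod1, Il1b and AC160336.1) for untreated against DMSO in CDK2-dTAG cells (49 as deposited) and 0 in WT cells, and 24 of 29 named values lost their call with no change of sign. Of the other named values, only Il1b in CDK2-dTAG cells passed (adjusted p = 0.0462 on the ratio). Cdk2 and Rpl41 were called by neither measure in either genotype. Differences of drug effects numbered 51 over all genes with a p-value and 0 with baseMean of 50 or more, against 3. Lists past the threshold for genotype in DMSO fell from 7 to 4 with ranks and to 4 with an inter-gene correlation of 0.05. For untreated against DMSO they went from 7 to 3 with that correlation in CDK2-dTAG cells, and with the ratio of group values from 7 to 4 there and from 4 to 2 in WT cells. Adjustment over all genes and a threshold of 0.1 gave counts within 1.5 times the deposited count in each of the 6 comparisons, for example 79 for genotype in DMSO at that threshold (61 as deposited). Depth is unknown, so its limit could not be given.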

Other observations

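Some lists moved without any called member. Mitochondrially encoded genes were higher in untreated than in DMSO CDK2-dTAG cells (15 genes, median log2 fold 0.25, cameraPR, adjusted p = 1.56e-05), and in WT cells the median was 0.05 (adjusted p = 0.179); the difference was not tested. The 37 tested neighbours of Cdk2 on its chromosome had a median log2 fold of 0.06 for WT over CDK2-dTAG in DMSO (adjusted p = 0.414), with 0 called.

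Among the tests below, those on the number of libraries and on repeat runs were chosen after the result was seen. The comparisons with DMSO and dTAG-13 were more precise than 3 libraries per group allow. Repeat runs of 3 libraries counted as 9 are argued against by the comparison of the untreated groups, which implied 2.40 libraries per group. The implied number of 9.01 is consistent with a model that pooled the libraries of 2, 6 and 24 h. The gap between the deposited fold and the ratio of group values correlated at 0.985 across 6716 genes between the genotypes, which an additive time term shared by all groups would give. A candidate explanation is therefore that columns headed 24 h hold averages over 3 times, so a drug effect present at a single time may be diluted; no biological explanation was tested.

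Inflammatory genes were higher in untreated than in DMSO cells by the deposited folds, and by less in the group values. Away from these genes, the slope of the untreated to DMSO ratio on the time shift was -0.10 in CDK2-dTAG and -0.03 in WT cells, below the bound of 0.5 set beforehand for untreated libraries away from the 24 h state. That bound could not separate the cases, since both simulated cases lay below it: untreated libraries at 24 h gave slopes of 0.26 in CDK2-dTAG and 0.21 in WT cells, and untreated libraries at the mean of the times gave -0.05 and -0.07. The observed slopes (standard errors 0.032 and 0.029) lay nearer to the latter. The simulations rest on an assumed layout and size of the time shift and on a wider set of genes, so this nearness does not settle the question. A vehicle effect of DMSO stays open too. The 35 of 35 called genes with the same sign in both genotypes do not support it, because both deposited folds contain the shared shift. These explanations cannot be told apart without values per library and time.

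Some granule genes were higher in CDK2-dTAG cells, and globin genes and Xist in WT cells. More neutrophils of all maturation stages in the CDK2-dTAG libraries stay open. The list's median of -0.13 (bootstrap 95% interval -0.18 to -0.03) lay above the bound of -0.2 set beforehand against them, but that bound took no account of the spread of the members: 7 of 30 were higher in WT cells, and the lower quartile of -0.31 reached the change of -0.3 that the explanation needs. Primary granule genes also moved in the same direction (median -0.14). More nucleated erythroid cells in WT libraries stay open (median without globin genes 0.14, interval -0.03 to 0.44), as does a different share of female mice (median of 4 Y-linked genes in DMSO -0.26, interval -1.78 to -0.14). These intervals resample the genes of a list, so they do not give the spread between libraries or mice. That of the Y-linked genes runs from the lowest member, Kdm5d, to the highest, Ddx3y. In untreated cells the Y-linked genes went both ways (Ddx3y -0.51, Kdm5d -0.44, Uty 0.12 and Eif2s3y 0.88 in the authors' deposited table), while Xist had a log2 fold of 2.08 there (authors' deposited table, adjusted p = 0.117). An effect of the tagged allele itself may also be the source and was not tested.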
